A study of Sorghum bicolor with 16 samples.

How the data were processed

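Poly(A) RNA from roots of 2 sweet sorghum strains was fragmented by the submitters and sequenced with and without enrichment by an m6A antibody, per the labels. Of the 16 samples, 2 belonged to each of the 8 combinations of strain, treatment and library type. The deposited files were 4 peak lists, 1 per strain and treatment and each of IP against input, and 1 expression table with 8 columns. The columns were assigned to samples by the sample descriptions, which place them with the IP samples. The names of the peak lists, however, give the columns' names to the samples that the IP samples were compared with. Whether the values of the columns were computed from IP or input fragments is not given in the sources used here. Nor are the peak caller, the pooling of replicates, the genome build and the annotation. The submitters' processing notes name cutadapt, FastQC, HISAT2, ChIPseeker, StringTie and edgeR, without roles.

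Per the file headers, the expression values are FPKM. The fold enrichment is the authors' ratio of IP over input in a peak, per the file headers. The score columns of the deposited lists hold the log10 of each peak's p value and of its false discovery rate, as a check of 1 column against the other showed. All log2 values were computed here from the deposited FPKM. Read totals were not used here, so depth was described only relative to M-81E control replicate 1, as the most frequent ratio of FPKM values under 0.5 (bins of 0.02 in log2). FPKM was not turned into counts, and no interval was given for single FPKM values. With 2 replicates per group, precision was carried by the spread pooled over all 4 groups.

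Expression was compared with limma 3.58.1 in R 4.3.3: log2(FPKM + 1), genes with a mean FPKM of at least 1 (16280 of them), 1 mean per strain and treatment, eBayes with a trend, and Benjamini-Hochberg adjusted p under 0.05. The contrasts were salt against control in each strain, the difference of these (interaction), and Roma against M-81E in control and in salt. The labels call the replicates biological and do not pair them, so no replicate block was used. The fit was tested on simulated data in which 200 of 16280 genes were changed between the Roma groups: 4, 58, 84 and 98% of genes changed by a log2 of 1, 2, 3 and 4 were recovered, and 7 of 129 calls were false. So an effect near a log2 of 1 was seldom recovered in the simulation. Whether these shares hold for the real data was not tested, so the share of false calls among the real calls is unknown. In the real data replicates differed with an SD in log2 of 1.09 and 0.918 in M-81E control and salt, against 0.744 and 0.779 in Roma. Of the 77 genes called for salt in Roma, 26 were listed at 0 in some library.

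Gene groups were tested with limma's camera at a preset correlation of 0.01, adjusted over groups and contrasts, with camera at an estimated correlation beside it. The groups fixed before the data were examined were defined by words in gene descriptions. Most descriptions in the table read hypothetical protein, so 22 of these 26 groups had fewer than 3 tested members and were not tested. A second set of 32 groups, defined by the annotated functions in the same table, was fixed after those columns had been read, and 31 were tested. Peaks were read in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Peaks were counted as shared when they overlapped by at least 1 bp on the same chromosome and strand. Shares carry exact 95% Clopper-Pearson intervals. Gene groups among genes with a peak were compared by a two-sided Fisher's exact test with all genes of FPKM at least 1 in that group of samples, adjusted over groups and lists. The share at matched expression was taken from genes of like FPKM.

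Genes named in the text were chosen by a rule fixed before the data were examined. For each salt response it takes the 10 largest rises and 10 largest falls past the threshold with a mean FPKM of at least 5, both salt libraries on the same side of both control libraries, and a described product. It takes 5 each way for the interaction and 3 each way for the strain contrast in control. Because few products are described, the rule was applied again to genes with an annotated activity, leaving out genes listed at 0 in some library. That addition was made after the zeros had been seen. From each group up to 4 members past the threshold were eligible, and of peaks the strongest per list and those listed in 1 condition. Genes called in both strains and the peaks on genes already named were picked out after their values had been seen.

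An exact FPKM of 0 was treated with care: a gene listed at 0 in a library and at FPKM 5 or more in another is described as listed at 0, with no fold. Comparisons, tests, thresholds and most alternatives were set before the data were examined. Alternatives set then were a pseudocount of 0.1, no filter or a filter of FPKM 5, quantile scaling, a replicate block, eBayes without a trend, a fit of only the 2 groups compared, each library left out in turn, stricter peak lists, a reciprocal overlap of 50% and equal numbers of strongest peaks. Leaving out genes listed at 0, alone or with M-81E control replicate 2, and an estimated correlation without that library were added after the data had been seen. First fits had also been run before those additions and the tests of explanations were written down. Sequence motifs in peaks were not analysed here, because no genome sequence was used.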

Results

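N6-methyladenosine (m6A) is a methyl mark on messenger RNA, and m6A-seq maps it by sequencing antibody-enriched RNA fragments (IP) beside unenriched fragments of the same RNA (input). Roots of 2 sweet sorghum strains at the 3-leaf phase were profiled with and without salt stress: M-81E, labelled salt-tolerant, and Roma, labelled salt-sensitive. Strain, treatment and library type (IP or input) gave 8 groups of 2 samples each, 16 in all, described as biological replicates. The salt dose and the length of the treatment are not given in the sources used here. Expression values were available for 8 libraries, 2 for each strain and treatment, and m6A peaks as 1 list per strain and treatment. The labels do not say whether the expression values came from IP or input fragments, so differences in expression between groups could not be separated from differences in enrichment.

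Read totals were not used here. The summed FPKM, an expression unit scaled by transcript length and library size, ranged from 325987 in M-81E control replicate 2 to 377097 in Roma control replicate 1. Between 14477 and 16006 genes per library reached FPKM 1. Relative sequencing depth, read from the ratios of low FPKM values and set to 1 in M-81E control replicate 1, ranged from 0.797 in M-81E control replicate 2 to 1.32 in M-81E salt replicate 1. The replicates of a group ranked genes most alike in Roma, with Spearman's rho across genes of 0.912 in control and 0.904 in salt. In M-81E rho was 0.864 in salt and 0.807 in control. The first principal component, with 35.7% of the variance, separated the strains, with M-81E at 44.1 to 61.5 and Roma at -58.7 to -49.0. On the second, with 19.7%, M-81E control replicate 2 stood alone at 94.6, and the other 7 libraries lay between -57.6 and 9.06.

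**Figure D1:**
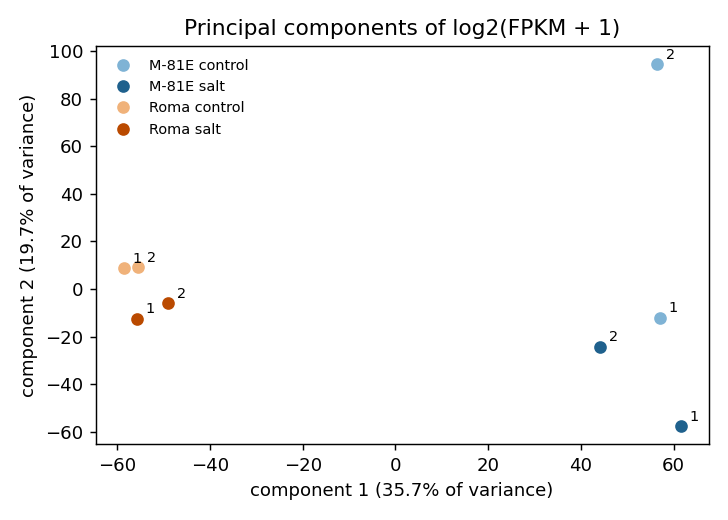
Each point is 1 library, numbered by replicate and coloured by strain and treatment; the axes are the first and second principal components of log2(FPKM + 1), without units. The strains lie apart on the first component, and M-81E control replicate 2 lies at 94.6 on the second.

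The first comparison asked which genes changed with salt in roots of M-81E. SORBI_3003G300600, annotated as a voltage-gated potassium channel, a class of protein that moves potassium across membranes, rose from an FPKM of 0.978 ± 0.0872 to 13.9 ± 1.31 (SD, n = 2), a log2 change of 2.91 (adjusted p = 0.0152). The catalase gene SORBI_3004G011566, whose product breaks down hydrogen peroxide, rose from 3.22 ± 0.890 to 14.8 ± 1.49, a log2 change of 1.92 (adjusted p = 0.0350). SORBI_3008G113000, an acid phosphatase, an enzyme class that releases phosphate, rose from 10.3 ± 5.10 to 73.2 ± 5.43 (log2 change 2.80, adjusted p = 0.0358). SORBI_3001G406300, a serine/threonine protein phosphatase in the annotated group of abscisic acid response, rose from 51.0 ± 5.35 to 201 ± 6.64 (log2 change 1.96, adjusted p = 0.0173). Other rises were those of a phosphoglycerate mutase of glycolysis, SORBI_3001G384100 (2.03), a transcription factor, SORBI_3002G253000 (1.89), a sugar transporter, SORBI_3001G373600 (1.73), and a drug transporter, SORBI_3001G454900 (1.61). SORBI_3006G081800, described as histone H3-like, was listed at 0 in both M-81E control libraries and at 12.1 and 9.05 in the salt libraries.

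The largest falls in M-81E among genes chosen by rule were those of 2 genes annotated as oxalate decarboxylases, enzymes that degrade oxalate. SORBI_3004G148100 fell from 129 ± 54.1 to 5.61 ± 0.285 (SD, n = 2; log2 change -4.23, adjusted p = 0.0117). SORBI_3007G067608 fell from 15.7 ± 9.34 to 0.221 ± 0.0770 (log2 change -3.65, adjusted p = 0.0326). The ubiquitin ligase gene SORBI_3007G056500, of a class that marks proteins for degradation, fell from 17.8 ± 4.25 to 0.867 ± 0.0563 (log2 change -3.31, adjusted p = 0.00642). A glycosyl hydrolase, SORBI_3007G219900 (-2.72), and a glycosyltransferase, SORBI_3006G122400 (-2.08), both in the annotated group of trehalose, raffinose and proline metabolism, also fell. So did a transcription factor, SORBI_3009G237600 (-2.38), and a ribose phosphate diphosphokinase of nucleotide synthesis, SORBI_3003G281200 (-2.26). Further falls were those of a ribosomal constituent, SORBI_3005G091700 (-1.80), an isomerase, SORBI_3007G023700 (-1.78), and a transporter, SORBI_3001G031700 (-1.32).

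In all, 80 of 16280 tested genes changed with salt in M-81E, 34 of them higher and 46 lower, and 2085 had an unadjusted p under 0.05. With only the 2 M-81E groups fitted 3 genes passed, 1 of them among the 80, and with a replicate block 22 did. Replicates differed with an SD in log2 of 1.09 and 0.918 in M-81E control and salt, against 0.744 and 0.779 in Roma. The spread pooled over all 4 groups was thus tighter than that of M-81E alone. Of the 80 genes, 35 were listed at 0 in some library and at FPKM 5 or more in another, and 35 were above 0 in every library. In the fit without M-81E control replicate 1 below, the only M-81E control is replicate 2, the library that lay apart. Calls kept in that fit are therefore no independent support. The count was 3082 without M-81E control replicate 1 and 120 without M-81E salt replicate 2. It was 42 without M-81E salt replicate 1, 37 and 32 without Roma control replicates 1 and 2, and 35 and 36 without Roma salt replicates 1 and 2. Of the 19 M-81E genes chosen by size of change, all passed without M-81E control replicate 1. Without M-81E control replicate 2, 10 did not pass: SORBI_3001G384100 (adjusted p = 0.0518), SORBI_3002G253000 (0.0600), SORBI_3001G373600 (0.0645), SORBI_3001G454900 (0.0600), SORBI_3007G219900 (0.0539), SORBI_3009G237600 (0.0545), SORBI_3003G281200 (0.0870), SORBI_3006G122400 (0.120), SORBI_3007G023700 (0.0953) and SORBI_3001G031700 (0.0545). Between 2 and 5 of the 19 passed when any 1 of the other 6 libraries was left out.

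Of 31 gene groups taken from the annotated functions of the genes, 10 were higher with salt in M-81E when each was tested against all other genes. All 10 calls were lost with a correlation between genes estimated from the data: adjusted p = 0.742 with an estimated correlation for flavonoid synthesis and adjusted p = 0.625 with an estimated correlation for the other 9. Of 41 genes of nitrate transport and assimilation, 33 had a positive change and 1 passed on its own, SORBI_3004G276200, which rose from 0.307 ± 0.239 to 4.08 ± 0.338 (SD, n = 2; log2 change 1.97); the median log2 change was 0.44 (adjusted p = 3.58e-05). Cell wall loosening and xyloglucan genes had a median of 0.50 over 59 members, none of which passed (adjusted p = 0.000126). Peroxidases, which act on phenolics and hydrogen peroxide in the wall, had a median of 0.48 over 114 members, 90 of them positive and none passing (adjusted p = 0.000153). Transcription factors had a median of 0.23 over 656 members, with 2 higher and 2 lower on their own (adjusted p = 0.000220): SORBI_3002G253000 and SORBI_3010G221400, listed at 0 in M-81E control, were higher, and SORBI_3009G088100 and SORBI_3002G139400, listed at 0 in M-81E salt, were lower. Suberin and Casparian strip genes, which seal the inner cell layers, had a median of 0.56 over 16 members, none passing (adjusted p = 0.00356). Water channels had a median of 0.50 over 24 members, none passing (adjusted p = 0.00406). Hypoxia response, with 41 members and none passing, had a median of 0.24 (adjusted p = 0.0154). Flavonoid synthesis had a median of 0.19 over 86 members (adjusted p = 0.0406), and its only member to pass, SORBI_3003G366700, was listed at 0 in both M-81E salt libraries. Lignin synthesis had a median of 0.29 over 73 members, none passing (adjusted p = 0.0406). Defense genes had a median of 0.09 over 184 members, of which 1 passed, SORBI_3001G406300 (adjusted p = 0.0412).

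M-81E control replicate 2 was lower than replicate 1 in these groups: the median log2 difference was -1.25 for water channels, -0.91 for peroxidases, -0.86 for cell wall loosening, -0.82 for flavonoid synthesis, -0.67 for lignin synthesis, -0.57 for suberin and Casparian strip, -0.43 for nitrate, -0.25 for hypoxia, -0.20 for transcription factors and -0.06 for defense. Without that library none of the 10 passed, and 3 of them turned: flavonoid synthesis (adjusted p = 0.455), lignin synthesis (0.815) and peroxidases (0.908), the last with a median still above 0 (0.0545). The medians were then 0.06 for cell wall loosening, 0.30 for suberin and Casparian strip, 0.13 for transcription factors, 0.05 for defense, -0.02 for lignin synthesis and -0.00273 for flavonoid synthesis. For water channels the median was then -0.0416 though the test's direction was up. Nitrate and hypoxia kept more of their change: with any 1 library left out their medians were at least 0.32 and 0.18, against 0.44 and 0.24 with all. The medians without M-81E control replicate 1 were 1.23 for water channels, 0.98 for cell wall loosening, 0.96 for peroxidases, 0.89 for nitrate, 0.89 for suberin, 0.63 for flavonoid synthesis, 0.60 for lignin synthesis, 0.39 for hypoxia, 0.36 for transcription factors and 0.16 for defense. Without M-81E salt replicate 2 they were 0.69 for nitrate, 0.38 for hypoxia and 0.30 for flavonoid synthesis, and without M-81E salt replicate 1 the median for defense was 0.18. Ribosomal proteins, not called with all libraries (median -0.11, adjusted p = 0.398), passed as lower without M-81E control replicate 2 (adjusted p = 0.000600), but not with an estimated correlation as well (adjusted p = 0.576). Without M-81E salt replicate 1, 5 of the 10 passed; without any 1 of the other salt libraries or the Roma control libraries, 9 did. With quantile scaling the call for flavonoid synthesis ended (adjusted p = 0.0610).

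Among the gene groups fixed before the data were examined, only 4 had enough tested members with a description to be tested. Dividing-cell markers, which are histones and cyclins, had a median log2 change of 1.08 in M-81E over 12 members, 11 of them positive (adjusted p = 0.000712; adjusted p = 0.512 with an estimated correlation). Their only member to pass was SORBI_3006G081800, listed at 0 in M-81E control, and adjusted over the list alone the count was again 1. The larger annotated group of nucleosome and mitosis genes, with 79 members and 30 of them positive, had a median of -0.24 in M-81E and did not pass (adjusted p = 0.225). The 3 antioxidant enzymes passed as a group (median 0.45, mean 0.92, adjusted p = 0.0173; adjusted p = 0.512 with an estimated correlation). The catalase SORBI_3004G011566 was their only member past the threshold, and 1 passed adjusted over the list alone. The larger annotated group of superoxide and peroxide removal, with 14 of 24 members positive and a median of 0.07, did not pass (adjusted p = 0.382). The medians for dividing-cell markers and antioxidant enzymes were 1.87 and 0.89 without M-81E control replicate 1, and 0.39 and 0.02 without replicate 2. Without M-81E control replicate 2 neither passed (adjusted p = 0.201 and 0.301), and without Roma salt replicate 2 only 1 of the pair did. In M-81E neither sucrose metabolism and transport, with 5 members (median -0.06, adjusted p = 0.862; 1 higher adjusted over the list alone), nor ribosomal proteins, with 28 (median -0.37, adjusted p = 0.175; 0 adjusted over the list alone), passed. Without M-81E control replicate 2 the ribosomal group passed as lower with salt (adjusted p = 0.000832), but not with an estimated correlation as well (adjusted p = 0.647).

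The next comparison asked the same of Roma. LEA3, SORBI_3009G215700, a late embryogenesis abundant protein of a family that accumulates in drying cells, rose from 1.61 ± 0.882 to 80.2 ± 15.2 (SD, n = 2), a log2 change of 4.99 (adjusted p = 0.0262). The malic enzyme gene SORBI_3003G292400, whose product converts malate to pyruvate, rose from 1.28 ± 0.614 to 55.7 ± 10.2 (log2 change 4.65, adjusted p = 0.00348). An aconitate hydratase of the citric acid cycle, SORBI_3002G316900, rose from 0.893 ± 0.159 to 21.6 ± 4.12 (log2 change 3.57, adjusted p = 0.00400). A proton-exporting ATPase, SORBI_3001G132400, of the class that energises transport across the plasma membrane, rose from 8.19 ± 0.336 to 98.1 ± 4.58 (log2 change 3.43, adjusted p = 0.00497). The phosphoglycerate mutase SORBI_3001G384100 rose from 2.13 ± 0.251 to 35.5 ± 5.24 (log2 change 3.54, adjusted p = 0.00448), and the catalase SORBI_3004G011566 from 10.7 ± 1.00 to 46.3 ± 2.64 (log2 change 2.02, adjusted p = 0.0267). Both oxalate decarboxylase genes rose, SORBI_3004G148100 from 1.02 ± 0.135 to 49.1 ± 12.7 and SORBI_3007G067608 from 0.418 ± 0.247 to 30.4 ± 3.61. A ribosomal constituent, SORBI_3001G383000 (3.18), a protein kinase, SORBI_3008G096200 (3.14), and a monooxygenase, SORBI_3003G228400 (3.11), also rose.

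The largest fall in Roma among genes chosen by rule was that of the beta-amylase SORBI_3001G293800, of an enzyme class that breaks down starch, from 58.3 ± 14.3 to 3.30 ± 1.103 (SD, n = 2; log2 change -3.79, adjusted p = 0.0202). A glutathione transferase, SORBI_3001G280800, of a detoxifying enzyme family, fell from 34.9 ± 1.17 to 10.9 ± 0.379 (log2 change -1.59, adjusted p = 0.0267). The glycosyl hydrolase SORBI_3007G219900 (-2.64), the glycosyltransferases SORBI_3006G122400 (-2.53) and SORBI_3002G334200 (-1.95), and the isomerase SORBI_3007G023700 (-2.43) fell as well. In all, 77 genes changed with salt in Roma, 54 higher and 23 lower, and 1924 had an unadjusted p under 0.05. With only the 2 Roma groups fitted 217 genes passed, 58 of them among the 77, and with a replicate block 44 did. Of the 77 genes, 26 were listed at 0 in some library and at FPKM 5 or more in another, and 49 were above 0 in every library. The count was 312 and 305 without M-81E control replicates 1 and 2, 45 without either Roma control library, and 35 and 26 without Roma salt replicates 1 and 2. All 17 Roma genes chosen by size of change passed without either M-81E control library, 10 without either M-81E salt library, 8 and 5 without Roma control replicates 1 and 2, and 5 and 3 without Roma salt replicates 1 and 2.

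**Figure D2:**
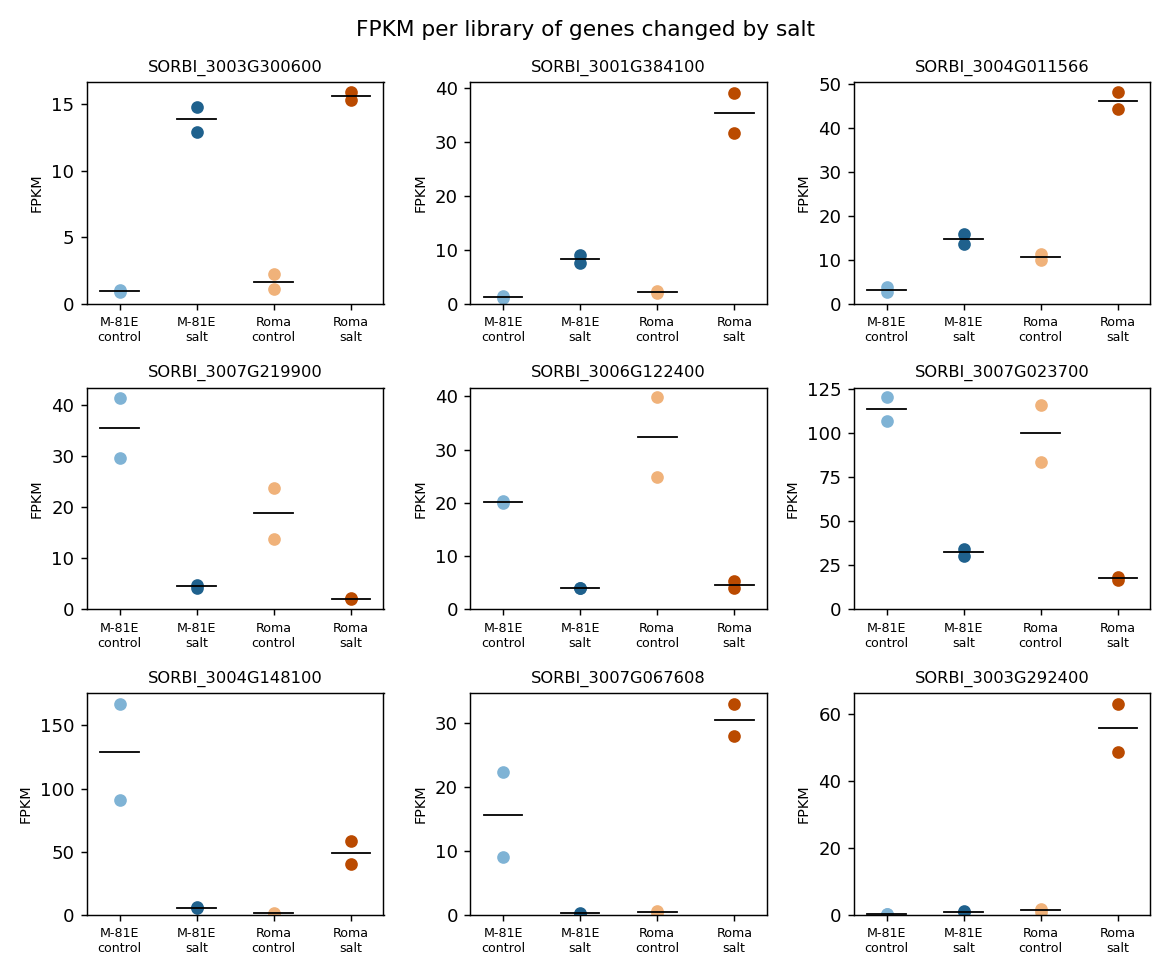
FPKM (vertical axis) of 9 genes by strain and treatment (horizontal axis); points are libraries and lines are means of 2. The potassium channel SORBI_3003G300600 is higher with salt in both strains, and SORBI_3004G148100 is lower with salt in M-81E (129 to 5.61) and higher in Roma (1.02 to 49.1).

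Of the annotated groups 3 were called in Roma, and all 3 calls were lost at adjusted p = 0.625 with an estimated correlation. Phosphate starvation genes were lower with salt, with a median log2 change of -0.48 over 25 members, of which 1 passed, SORBI_3001G054000, from 7.85 ± 0.546 to 2.08 ± 0.227 (SD, n = 2; group adjusted p = 0.00307). Ribosomal proteins had a median of -0.26 over 309 members (adjusted p = 0.0180), although the only member to pass, SORBI_3001G383000, rose. Sodium and potassium transport had a median of 0.12 over 57 members (adjusted p = 0.0455), with 2 passing: the channel SORBI_3003G300600 and the transporter SORBI_3004G260500, from 1.24 ± 0.255 to 14.8 ± 0.895 (log2 change 2.82). M-81E control replicate 2 differed from replicate 1 by a median log2 of 0.40 for sodium and potassium transport, 0.13 for phosphate starvation and -0.28 for ribosomal proteins. Without it the sodium and potassium call ended. That library does not enter the salt change in Roma, however. With any 1 library left out the median for sodium and potassium transport stayed between 0.093 and 0.16. Without Roma control replicate 1 or Roma salt replicate 2 only 1 of the 3 passed, and without Roma control replicate 2 or either M-81E salt library 2 did. The ribosomal group fixed beforehand, with 28 members and a median of -0.29, was lower too (adjusted p = 0.0128; adjusted p = 0.512 with an estimated correlation; 0 adjusted over the list alone), except without Roma salt replicate 2. Without that library the median of the 309 ribosomal proteins was -0.17. Antioxidant enzymes (median 0.22, adjusted p = 0.124; 1 adjusted over the list alone, the catalase), dividing-cell markers (0.04, 0.420; 0 adjusted over the list alone) and sucrose metabolism and transport (-0.20, 0.220; 0 adjusted over the list alone) did not pass in Roma.

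Some genes were called in both strains. The potassium channel SORBI_3003G300600, the catalase SORBI_3004G011566, the phosphoglycerate mutase SORBI_3001G384100 and the sugar transporter SORBI_3001G373600 rose in both. The glycosyl hydrolase SORBI_3007G219900, the glycosyltransferase SORBI_3006G122400, the isomerase SORBI_3007G023700 and SORBI_3003G370600, which has no described function, fell in both. With genes listed at 0 included, 5 genes rose in both, 7 fell in both and 4 moved in opposite directions. The genes listed at 0 among these were SORBI_3010G096700, which was higher in both, and SORBI_3002G113500, SORBI_3004G231200 and SORBI_3010G261100, which were lower in both. The opposite ones were the oxalate decarboxylases SORBI_3004G148100 and SORBI_3007G067608, SORBI_3008G090600, and SORBI_3009G030100, listed at 0. Independent calls would give 0.113 genes higher in both and 0.0650 lower in both. Both calls use the same spread for each gene, pooled over all 4 groups, so they are not independent. A Fisher's exact test of the overlap (p = 2.54e-22) assumes that they are, so its p does not measure how far the strains share a response. The correlation of the log2 changes of the strains across all tested genes was 0.119, and 0.190 without genes listed at 0.

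Whether a salt response differed between the strains was tested directly, as the Roma change minus the M-81E change. The oxalate decarboxylase genes moved in opposite directions: the difference in log2 change was 8.84 for SORBI_3004G148100 (adjusted p = 0.00358) and 8.13 for SORBI_3007G067608 (adjusted p = 0.0106). Their levels with salt were 5.61 ± 0.285 and 0.221 ± 0.0770 in M-81E and 49.1 ± 12.7 and 30.4 ± 3.61 in Roma (SD, n = 2). Reads shared between these related genes were not examined. The malic enzyme SORBI_3003G292400 rose by 3.85 more in Roma (adjusted p = 0.0300), from 0.133 ± 0.00396 to 0.978 ± 0.256 in M-81E. Both M-81E means lay under FPKM 1, so the size of the difference depends in part on the pseudocount. Without M-81E control replicate 2 this call ended. The ubiquitin ligase SORBI_3007G056500 fell in M-81E and was at 14.6 ± 0.197 and 14.4 ± 1.52 in Roma control and salt, a difference of 3.29 (adjusted p = 0.0271). The histone H3-like SORBI_3006G081800, listed at 0 in M-81E control, was at 16.2 and 12.8 in Roma control and 15.2 and 13.8 in Roma salt. In all, 29 genes differed in their response, 21 of them with the higher change in Roma and 8 with the lower, and 1421 had an unadjusted p under 0.05. Of the 29, 22 were listed at 0 in some library and at FPKM 5 or more in another, and 5 were above 0 in every library. The count was 1074 and 97 without M-81E control replicates 1 and 2, 90 without M-81E salt replicate 2, 10 and 18 without Roma control replicates 1 and 2, and 18 without Roma salt replicate 2. Of the 5 genes named here all passed without M-81E control replicate 1, 4 without replicate 2, 1 and 3 without M-81E salt replicates 1 and 2, 1 without either Roma control library, and 2 and 1 without Roma salt replicates 1 and 2.

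Several genes past the threshold in 1 strain were not shown to respond differently. For the late embryogenesis abundant SORBI_3009G215700 the log2 change in M-81E was 2.87 (adjusted p = 0.144; interaction adjusted p = 0.502). For the proton ATPase SORBI_3001G132400 it was 1.51 (0.0776; interaction 0.152), and for the beta-amylase SORBI_3001G293800 it was -0.08 (0.945; interaction 0.107). The aconitate hydratase SORBI_3002G316900 (interaction adjusted p = 0.0675), the acid phosphatase SORBI_3008G113000 (0.0691), the glutathione transferase SORBI_3001G280800 (0.0785) and the phosphatase SORBI_3001G406300 (0.203) also missed the threshold. Without M-81E control replicate 2 SORBI_3008G113000 (0.0151) and SORBI_3001G280800 (0.0468) passed.

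Of the annotated groups 8 had lower salt changes in Roma than in M-81E, and all 8 calls were lost at adjusted p = 0.625 with an estimated correlation. They included peroxidases (median difference -0.71, adjusted p = 6.82e-06) and cell wall loosening genes (-0.72, 1.26e-05). Water channels (-0.95, 0.000274), lignin synthesis (-0.63, 0.00307) and suberin and Casparian strip genes (-0.77, 0.00356) were lower too. The same held for phosphate starvation (-0.27, 0.0180), nitrate transport and assimilation (-0.49, 0.0193) and hypoxia response (-0.56, 0.0260). In none of these 8 groups did a member pass on its own. M-81E control replicate 2 differed from replicate 1 by a median log2 of -1.25 for water channels, -0.91 for peroxidases, -0.86 for cell wall loosening, -0.67 for lignin, -0.57 for suberin, -0.43 for nitrate, -0.25 for hypoxia and 0.13 for phosphate starvation. Without that library none of the 8 passed (adjusted p from 0.112 for phosphate starvation to 0.536 for nitrate). The median differences were then -0.27 for water channels, -0.24 for peroxidases, -0.34 for cell wall loosening, -0.22 for lignin, -0.38 for suberin, -0.17 for nitrate and -0.22 for hypoxia. For phosphate starvation the difference did not shrink, at -0.31 against -0.27 with all libraries. With replicate 1 left out instead they were -1.70 for water channels, -1.18 for peroxidases, -1.23 for cell wall loosening, -0.97 for lignin and -0.0248 for phosphate starvation. The difference was -0.31 for nitrate without Roma control replicate 2, and for hypoxia -0.36 without Roma control replicate 1 and -0.35 without M-81E salt replicate 1. Without M-81E salt replicate 1, 6 of the 8 passed. Without M-81E control replicate 1, M-81E salt replicate 2, Roma control replicate 2 or Roma salt replicate 1, 7 did. Dividing-cell markers, fixed beforehand, had a median difference of -1.03 (adjusted p = 0.0128; adjusted p = 0.512 with an estimated correlation; 1 higher and 1 lower adjusted over the list alone). The larger group of nucleosome and mitosis genes had a median difference of 0.02, with 42 of 79 members positive (adjusted p = 0.954), and the test's direction was down. For dividing-cell markers the median difference was -1.60 without M-81E control replicate 1, -0.38 without replicate 2 and -0.55 without M-81E salt replicate 1. Their call ended without M-81E control replicate 2 (adjusted p = 0.356), and also without M-81E salt replicate 1 or Roma salt replicate 2. Antioxidant enzymes (-0.15, 0.586; 0 adjusted over the list alone), ribosomal proteins (0.08, 0.546; 0 adjusted over the list alone) and sucrose metabolism and transport (-0.21, 0.175; 0 adjusted over the list alone) did not pass; for ribosomal proteins the test's direction was down though the median was above 0.

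The strains differed in many more genes than either changed with salt. In control the GID1-like gibberellin receptor SORBI_3009G134600, which senses a growth hormone, stood at 5.09 ± 1.55 in M-81E and 124 ± 7.32 in Roma (SD, n = 2), a log2 difference of 4.38 (adjusted p = 0.00489). A protein kinase, SORBI_3005G069900, was at 0.338 ± 0.124 in M-81E and 45.0 ± 1.09 in Roma (5.11, adjusted p = 0.000468). The esterase PIR7B, SORBI_3003G417350 (3.77), an acid phosphatase, SORBI_3009G071300 (4.65), and an aspartic endopeptidase, SORBI_3002G243000 (4.48), were also higher in Roma. Higher in M-81E were a transcription factor, SORBI_3007G047400, at 52.2 ± 14.5 against 0.351 ± 0.00335 (log2 difference -5.27, adjusted p = 0.000632), and the oxalate decarboxylase SORBI_3004G148100 (-5.94). A dirigent-type gene, SORBI_3002G100832, of a family that directs lignan coupling (-5.14), an isoflavone reductase homolog, SORBI_3008G106800 (-3.91), SORBI_3005G093400, of unknown function (-2.66), and the transcription factor TGA6, SORBI_3009G155050 (-1.63), were higher in M-81E too. With salt, the kinase SORBI_3005G069900 (5.50, adjusted p = 0.000412) and the transcription factor SORBI_3007G047400 (-4.95, adjusted p = 0.000653) still differed.

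In control 1971 genes differed between the strains, 1359 higher in Roma and 612 lower, and 5243 had an unadjusted p under 0.05. With salt 1370 differed, 977 higher in Roma and 393 lower, and 4766 had an unadjusted p under 0.05. The median of all tested genes was itself higher in Roma by a log2 of 0.30 in control and 0.29 with salt, against 0.03 and 0.05 after quantile scaling. After that scaling the control count of 1515 split into 696 higher and 819 lower, and the salt count of 1031 into 503 higher and 528 lower. The control count was 4189 and 3862 without M-81E control replicates 1 and 2, 267 and 257 without Roma control replicates 1 and 2, and 852 and 833 without Roma salt replicates 1 and 2. The salt count was 4134 and 4114 without M-81E control replicates 1 and 2, 536 and 529 without the Roma control libraries, 255 and 228 without the Roma salt libraries, and 406 and 767 without M-81E salt replicates 1 and 2. Of the 12 genes chosen for the control contrast, which include SORBI_3006G081800, listed at 0 in M-81E control, all passed without either M-81E salt library. Without M-81E control replicates 1 and 2, 11 and 10 passed, 8 without either Roma control library and 9 without either Roma salt library.

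The m6A landscape of each group was described from the authors' peak lists, whose fold enrichments and p values are the authors' own and serve only to rank and describe peaks. Each list covers both replicates without separate values, so no replicate error is given, and the 95% exact (Clopper-Pearson) intervals below cover counting error only. The M-81E control list therefore includes replicate 2, which lay apart in expression, and its part in the listed peaks cannot be told. M-81E had 10219 peaks in 8143 genes in control and 10255 in 8432 genes with salt. Roma had 5949 peaks in 5221 genes in control and 12080 in 9843 genes with salt. The median fold enrichment of IP over input was 12.8 and 12.9 in M-81E control and salt, and 18.0 and 21.4 in Roma. Median peak width was 241 and 257 bp in M-81E and 238 and 269 bp in Roma. Of genes with FPKM of at least 1, a peak was listed for 50.6% (interval 49.8 to 51.4) in M-81E control and 51.6% (50.8 to 52.4) in M-81E salt. In Roma the share was 31.1% (30.4 to 31.8) in control and 56.8% (56.0 to 57.6) with salt. A peak in all 4 lists was found for 4584 genes, out of 11065 with a peak in any.

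**Figure D3:**
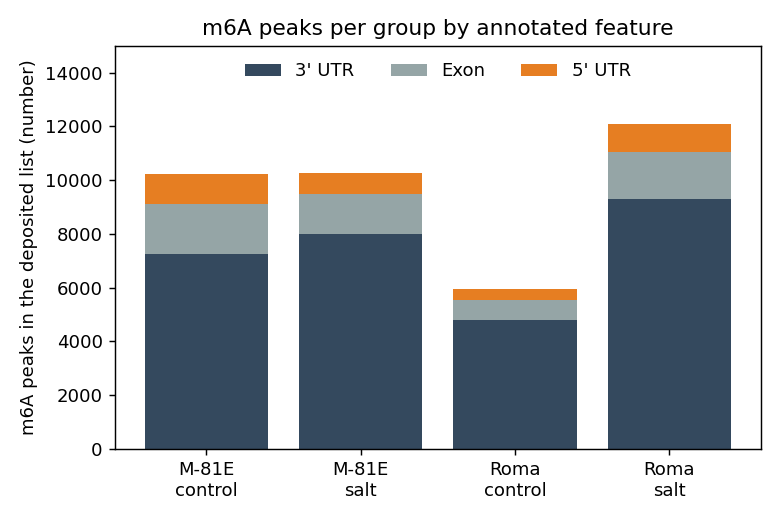
Number of m6A peaks (vertical axis) in the deposited list of each strain and treatment (horizontal axis), stacked by annotated feature. Roma control has 5949 peaks and the other lists have 10219 to 12080, most of them in 3' UTRs.

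Peaks lay mostly near the 3' ends of transcripts in every group. In M-81E control 71.1% of peaks were annotated to 3' UTRs, 18.0% to other exons and 10.9% to 5' UTRs. In M-81E salt the 3' UTR share was 77.9% (interval 77.1 to 78.7) and the 5' UTR share 7.40% (6.90 to 7.93, against 10.3 to 11.5 in control). In Roma the 3' UTR share was 80.4% in control and 77.1% with salt, and the 5' UTR share 6.79% and 8.60%. The median distance to the annotated 3' end was 300.5 and 268 bp in M-81E and 258.5 and 269 bp in Roma, control and salt in turn. The strongest peak of a described gene in M-81E control, with a fold of 11300, lay in the 3' UTR of the cytochrome P450 gene SORBI_3002G346250 on chromosome 2 (71221381 to 71221760). The expression table lists that gene at 0 in both M-81E control libraries. A glycosyltransferase, SORBI_3009G063400, had a 5' UTR peak on chromosome 9 (6751513 to 6751813) with a fold of 5750 in M-81E control. A protein kinase, SORBI_3003G113800, had a 5' UTR peak on chromosome 3 (10257926 to 10258284) with a fold of 4480 in Roma salt and one with a fold of 3820 in Roma control. The myosin-6-like SORBI_3004G344901, a cytoskeletal motor, had a 3' UTR peak on chromosome 4 (67507713 to 67507982) with folds of 684 in M-81E salt and 1340 in Roma salt. The genome build is not given in the sources used here.

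Most M-81E peaks were listed in both conditions, and fewer of the weaker than of the stronger Roma salt peaks were listed in control. In M-81E 81.1% of control peaks (interval 80.3 to 81.8) overlapped a salt peak, and 81.2% of salt peaks overlapped a control peak. Of M-81E control peaks 89.6% in 3' UTRs were found again with salt, but 58.4% (55.5 to 61.3) in 5' UTRs and 61.2% in other exons. Whether the control peaks not found again came from M-81E control replicate 2 was not tested. Of M-81E salt peaks 81.8, 83.0 and 77.3% in 3' UTRs, 5' UTRs and other exons were found in control. In Roma these shares were 97.45, 89.9 and 91.3% of control peaks and 50.5, 39.5 and 32.1% of salt peaks. In Roma 96.2% of control peaks overlapped a salt peak, but 46.9% of salt peaks (46.0 to 47.8) overlapped a control peak. Ranked by peak p, 4.97% of the weakest 10% of Roma salt peaks and 99.3% of the strongest 10% were found in control; in M-81E these shares were 33.4% and 99.8%. With only the 5949 strongest peaks of each list compared, the Roma salt share was 78.3% and the M-81E salt share 83.8%. Between strains 51.4% of M-81E control peaks overlapped a Roma control peak, and 87.4% of M-81E salt peaks overlapped a Roma salt peak. Of Roma peaks 89.3% in control and 73.6% with salt overlapped an M-81E peak. Replicate peak lists were not used here, so none of these shares was tested between groups.

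**Figure D4:**
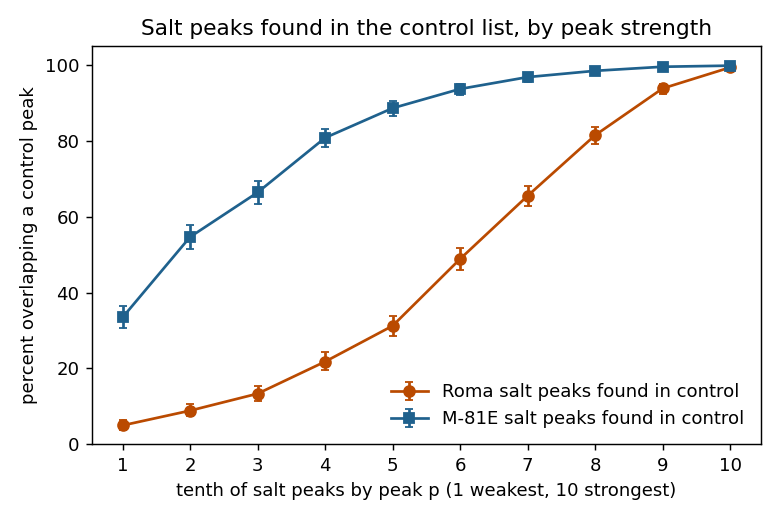
Percent of salt peaks that overlap a control peak (vertical axis) by peak strength in 10 classes of like size from weakest to strongest (horizontal axis), for each strain; bars are exact 95% intervals. The Roma share rises from 4.97% to 99.3% and the M-81E share from 33.4% to 99.8%.

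Single genes carried peaks listed in 1 condition. In M-81E the histone H3.2-like SORBI_3010G047100 (chromosome 10, 3658064 to 3658267, fold 40.7) and the histone H4-like SORBI_3001G313200 (chromosome 1, 60038023 to 60038285, fold 10.2) had 5' UTR peaks in control and none with salt. That control list includes M-81E control replicate 2. In Roma SORBI_3010G047100 had a peak with salt (fold 119) and none in control. The pathogenesis-related PR10c gene SORBI_3001G400800 had a 5' UTR peak in control and none with salt in both strains (chromosome 1, 68616435 to 68616703 in M-81E, fold 8.91; fold 18.8 in Roma). CIPK25, SORBI_3002G417300, a kinase of calcium signalling, had a 3' UTR peak in M-81E salt (chromosome 2, 76455700 to 76456000, fold 6.52). Glutamine synthetase, SORBI_3001G116400, had one there too (chromosome 1, 9075636 to 9075815, fold 5.61). Both folds lay under the median of 12.9 in that list. The FPKM of SORBI_3001G116400 was 5.05 in M-81E control and 23.2 with salt. In M-81E control a peak was listed for 44.4% of genes with FPKM from 3 to 10, so lower expression may hide one. In Roma salt an allantoinase of purine breakdown, SORBI_3006G270100, had a 3' UTR peak with a fold of 592 (chromosome 6, 60250299 to 60250686). The 2 genes annotated to mRNA methylation did not change with salt beyond error: SORBI_3004G033100 had log2 changes of -0.07 in M-81E (adjusted p = 0.883) and -0.14 in Roma (0.832), and SORBI_3004G285000 of -0.27 (0.600) and 0.92 (0.185; interaction 0.372). SORBI_3004G033100 itself carried a 3' UTR peak in all 4 lists, with folds of 172 and 383 in M-81E control and salt and 387 and 403 in Roma. SORBI_3004G285000 had a 3' UTR peak in M-81E control and salt (folds of 12.7 and 5.19) and in Roma salt (15.8), but none in Roma control.

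Genes with a peak were the more highly expressed ones. With FPKM averaged over the 2 libraries, the median log2(FPKM + 1) of genes with a peak was higher than that of genes without by 1.77 in M-81E control, 1.67 in M-81E salt, 1.95 in Roma control and 1.72 in Roma salt. Computed per library, the difference was 1.70 and 1.81 in M-81E control and 1.62 and 1.71 in M-81E salt. In Roma it was 1.95 and 1.94 in control and 1.70 and 1.72 with salt. In M-81E control a peak was listed for 4.04% of genes with FPKM from 0.1 to 1 and for 87.4% of genes with FPKM of at least 100; in Roma control for 1.88% and 81.1%. Genes are not replicates, and both FPKM and peak calling depend on read depth. Whether the FPKM came from IP or input fragments is not stated, and FPKM from IP fragments would itself be higher in genes with a peak.

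A peak gained or lost under salt went with little change in expression. In M-81E 1295 genes had a peak with salt and none in control and 1006 the reverse, and their expression changes did not differ from those of other genes (limma's camera, adjusted p = 0.641 for both). In Roma 4751 genes had a peak with salt and none in control (adjusted p = 0.263), and 129 the reverse. Of the 129, 110 were tested: their median log2 change was -0.24 against -0.03 in other genes (adjusted p = 0.00400; adjusted p = 0.0359 with an estimated correlation), and none was called on its own. With only peaks above the pooled median fold of 15.8 counted, the difference from other genes was -0.17 and no longer past the threshold. Of the 54 genes that rose in Roma, 27 had a peak with salt and 8 in control, and of the 23 that fell, 7 had one with salt and 5 in control. In M-81E 9 of 34 genes that rose had a peak with salt and 8 in control, and of 46 that fell 16 had one in each. Of all 16280 tested genes 9280 had a peak with salt and 5049 in control in Roma, and 8035 and 7764 in M-81E. The malic enzyme SORBI_3003G292400, the aconitate hydratase SORBI_3002G316900, the proton ATPase SORBI_3001G132400, the phosphoglycerate mutase SORBI_3001G384100 and the catalase SORBI_3004G011566, which rose in Roma, had a peak only in the Roma salt list of the 4 lists. So did the glycosyltransferase SORBI_3006G122400, which fell there. The malic enzyme, the aconitate hydratase and the mutase were below FPKM 3 in Roma control. There a peak was listed for 6.35% of genes with FPKM from 1 to 3 and 1.88% from 0.1 to 1, so low expression may hide one. Other genes that rose in Roma differed: SORBI_3001G383000 had a peak only in M-81E control, and LEA3, SORBI_3009G215700, in M-81E control, M-81E salt and Roma salt. The ubiquitin ligase SORBI_3007G056500 had a 3' UTR peak in all 4 lists, with folds of 16.7 and 23.0 in M-81E control and salt and 47.3 and 28.5 in Roma.

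Some gene groups carried peaks more often than other genes with FPKM of at least 1. Ribosomal proteins had a peak for 68.4% of members in M-81E control (adjusted p = 1.89e-08, Fisher's exact test), 72.2% in M-81E salt (1.50e-11), 57.3% in Roma control (1.25e-19) and 78.2% in Roma salt (1.56e-13), against 50.6, 51.6, 31.1 and 56.8% of all such genes. Genes of matched expression had a peak for 61.5, 61.1, 46.6 and 67.8%. The smaller ribosomal group fixed beforehand passed in M-81E salt (82.1%, adjusted p = 0.00896) and Roma control (66.7%, adjusted p = 0.00327), but with FPKM of at least 5 as background in neither (adjusted p = 0.812 and 0.0643). Peroxidases had a peak for 34.0, 25.9, 18.9 and 29.7% of members in M-81E control and salt and Roma control and salt, where genes of matched expression had one for 57.4, 59.98, 38.8 and 61.4%. Cell wall loosening genes (18.6, 18.2, 10.8 and 22.2%) and glutathione transferases (30.1, 31.1, 15.8 and 29.3%) were also below the background in all 4 groups. Over 31 groups and 4 lists, 48 tests of this added set passed, and 2 of those fixed beforehand. Genes in a group are not independent, so these p values are descriptive.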

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

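The tests of failed expression estimates, of loss at random and of loss in genes prone to it, of peaks near the detection limit and of shallower Roma control libraries were chosen after the results they measure had been seen, and the condition that the mixture test weigh its spread was added after its value had been seen.

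Salt responses that differed between the strains by the test of the difference itself were picked out here. They were 29 genes as a count. Of the genes chosen by rule, the difference in log2 change, Roma minus M-81E, was 8.84 for the oxalate decarboxylase SORBI_3004G148100 and 8.13 for SORBI_3007G067608, 3.85 for the malic enzyme SORBI_3003G292400 and 3.29 for the ubiquitin ligase SORBI_3007G056500. The malic enzyme had both M-81E means under FPKM 1, so the size of its difference depends in part on the pseudocount. For the histone H3-like SORBI_3006G081800, listed at 0 in both M-81E control libraries, the fitted difference was -3.51 and depends on the pseudocount. Of gene groups, the median differences were -0.95 for water channels, -0.77 for suberin and Casparian strip, -0.72 for cell wall loosening, -0.71 for peroxidases, -0.63 for lignin synthesis, -0.56 for hypoxia response, -0.49 for nitrate transport and assimilation and -0.27 for phosphate starvation. For dividing-cell markers the median difference was -1.03, but 0.02 for the larger group of nucleosome and mitosis genes, which did not pass. None of these group differences passed with an estimated correlation or without M-81E control replicate 2. Without that library the differences that had passed were smaller, except that of phosphate starvation, at -0.31.

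Of the 29 genes, 22 were listed at 0 in some library and at FPKM 5 or more in another, and genes listed at 0 in both libraries of a group were looked at over all 4 groups. Among 612 such cases with FPKM of at least 5 elsewhere, 32.5% had an m6A peak in the same group, against 54.3% of genes of like expression and 0.613% of genes at 0 in both libraries and under FPKM 1 elsewhere, which replaced genes at 0 in all 8 libraries, of which there were 0. Loss at random in genes of like abundance is argued against, since pairs of libraries of the same group shared 170 to 236 such genes, where independent loss gave a mean of at most 18.5 and an upper limit of at most 28 for any pair. Peaks on transcripts listed at 0 are consistent with failed expression estimates for part of these genes, less so in Roma control, where 12.2% had a peak against 38.6% at like expression. Loss library by library in genes prone to it cannot be told apart, because 2 of the 4 pairs of the same group lay above the 150 to 224 shared by pairs of different groups, but not by 1.5 times, and neither can merging of adjacent loci, because 13.5% of these genes had a neighbour listed at 0, above the 10.1% upper limit of random draws but under 2 times their mean of 7.82%; absence of the transcript in 1 strain or treatment stays open and was not tested.

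The groups higher with salt in M-81E did not pass without M-81E control replicate 2. For nitrate and hypoxia the median was still at least 0.32 and 0.18 with any 1 library left out, against 0.44 and 0.24 with all. M-81E control replicate 2 lay apart from replicate 1. Lower depth alone is argued against: among genes with a mean FPKM of at least 30 the replicates differed with an SD of 1.07 in log2, against at most 0.820 in the other groups, although its relative depth of 0.797 was close to the 0.820 of Roma salt replicate 2. RNA of the other strain cannot be told apart: 58.4% of 3952 genes separating the strains in salt lay nearer to M-81E in it, against 88.2% in replicate 1 and 17.4 and 18.4% in the Roma control libraries. A mixture test added after that value came out between its bounds found 7 genes seen only in Roma at a median of 1.53% of their Roma level (quartiles 0.278 to 10.8%, 2 of them at 10% or more), under the bound of 2% set for no mixture but not by more than this spread, and 4 genes seen only in M-81E at a median of 0% of their replicate 1 level, while the first principal component placed the library with M-81E at 56.4. The log2 values of M-81E control replicate 2 correlated at 0.757 to 0.774 with the Roma libraries, against 0.799 to 0.810 for replicate 1. So it was not nearer to Roma as a whole. With the M-81E salt libraries it correlated at 0.773 and 0.821, also under the 0.860 and 0.897 of replicate 1. These values therefore do not settle a partial mixture. Shoot tissue cannot be told apart either, with photosynthesis genes at a median difference of 0.02 (0.0193) and 15 of 27 higher. A biological difference between the plants sampled stays open and was not tested.

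Roma control had 5949 peaks where the other lists had 10219 or more. Missed peaks near the detection limit would give the overlap seen, which rose from 4.97% of the weakest 10% of Roma salt peaks to 99.3% of the strongest 10%. It rose in M-81E too, from 33.4% to 99.8%, with lists of like size, so the rise does not single out this cause. Ranked by fold enrichment instead of peak p, the peaks absent from Roma control were not all at the low end. Of 4751 genes with a peak in Roma salt and none in Roma control, 2483 had one above the pooled median fold of 15.8. That fold lay under the Roma salt median of 21.4, and 7209 of all 12080 Roma salt peaks were above it. So these genes did not stand out by a high fold, and their folds do not count against missed peaks. Of Roma salt peaks above that fold, 42.2% were found among the Roma control peaks above it, a share that leaves out control peaks of lower fold. Shallower Roma control libraries in the expression table are argued against, since their summed relative depth was 1.198 times that of the Roma salt libraries, which says nothing of the depth of the libraries behind the peaks if these were others. Methylation gained under salt in Roma cannot be told apart, because 54.3% of the Roma salt peaks absent from Roma control overlapped an M-81E control peak, and a site marked in M-81E may still be gained in Roma. Replicate peak lists were not used here, so a gain was not told from a weaker enrichment in the Roma control libraries.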

How the results depend on the processing

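Alternatives that left out genes listed at 0, alone or with M-81E control replicate 2, or that joined leaving out that library with an estimated correlation, were chosen after the data had been seen. The cause was not tested for the changes below, except that fewer genes, groups or libraries enter some of the fits by construction. No gene chosen by rule reversed under any alternative run, but many lost their call. Of 53 calls of such genes 24 were lost with a replicate block, 14 without a filter, 11 at FPKM 5, 7 with a pseudocount of 0.1, 5 with quantile scaling and 1 without a trend. With only the 2 groups fitted 24 of 48 were lost, and of 50 calls 4 were lost without genes listed at 0 and 17 also without M-81E control replicate 2. With 1 library left out 1 to 37 of the 53 were lost. Apart from the counts and shares of the comparisons, 898 values kept their direction and side of the threshold, 432 kept the direction and lost the call, and 10 reversed; of the counts, shares and peak sets 150 stayed alike, 111 moved, 3 reversed and 1 lost its call.

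Genes changed by salt in M-81E (80) numbered 34 with a mean FPKM of at least 5, 22 with a replicate block, 3 with only the 2 groups fitted, 48 without genes listed at 0 and 13 also without M-81E control replicate 2. Genes changed in Roma (77) numbered 130 without a filter, 30 at FPKM 5, 44 with the block, 217 with only the 2 groups and 455 without genes listed at 0 and that library. Interaction genes (29) numbered 50 without a filter, 5 at FPKM 5, 10 with the block, 4 without genes listed at 0 and 3 also without the library. Strain differences in control (1971) numbered 1047 at FPKM 5, 296 with only the 2 groups, and 4222 without genes listed at 0 and the library. In salt (1370) they numbered 654 at FPKM 5, 803 with the block and 4440 without genes listed at 0 and the library. The replicate numbers did not pair the groups: correlations of replicate deviations across groups lay from -0.038 to 0.038.

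With 1 library left out, the lone sample of its group is assumed to vary like the other groups. Counts then ranged from 32 to 3082 for salt in M-81E, 26 to 312 for salt in Roma, 10 to 1074 for the interaction, 257 to 4189 for strains in control and 228 to 4134 for strains in salt. The lowest values came without a Roma library and the highest without M-81E control replicate 1, the other member of the most different pair. Gene groups fixed beforehand that moved (4) numbered 1 to 5, added groups 1 to 14 in M-81E (10), 1 to 4 in Roma (3) and 0 to 11 for the interaction (8).

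With an estimated correlation 0 groups fixed beforehand passed, and 0 added groups in M-81E, 0 in Roma and 0 for the interaction, and all 4 counts were again 0 with M-81E control replicate 2 left out too, where peroxidases (0.0545), lignin synthesis (-0.0163) and flavonoid synthesis (-0.00273) turned down in M-81E. Without genes listed at 0 and M-81E control replicate 2, 2 groups fixed beforehand passed, 1 added group in M-81E and 0 for the interaction. In that setting 4 groups in M-81E turned down, with median log2 changes of -0.0739 for water channels, 0.0855 for peroxidases (the test's direction was down though the median was above 0), -0.00634 for lignin synthesis and -0.000955 for flavonoid synthesis. With 1 library left out these medians ranged from 0.0545 to 0.96 for peroxidases, -0.0163 to 0.60 for lignin synthesis and -0.00273 to 0.63 for flavonoid synthesis. For genes that gained or lost a peak in M-81E the difference from other genes ranged from -0.0277 to 0.0569 and from -0.11 to 0.11. For genes that lost a peak in Roma it was -0.17, no longer past the threshold, when only peaks above the pooled median fold of 15.8 were counted.

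Above that fold the lists held 4408 and 4370 peaks in M-81E control and salt and 3229 and 7209 in Roma, with 74.9, 88.7, 86.4 and 85.7% in 3' UTRs. Control peaks found with salt were 68.4% in M-81E and 94.3% in Roma above that fold, 71.1 and 72.5% at a reciprocal overlap of 50%, and 83.4 and 79.5% among the 5949 strongest of each list. Salt peaks found in control were 69.2 and 42.2%, 70.9 and 35.7%, and 83.8 and 78.3% in the same order. M-81E peaks found in Roma were 41.2% in control and 76.0% in salt at the reciprocal overlap, 71.9 and 82.0% among the strongest, and 89.95% in salt above that fold. The log2 expression difference between genes with and without a peak was 3.36, 3.21, 3.60 and 3.20 without a filter, 2.01, 1.91, 2.14 and 1.97 with a pseudocount of 0.1, and 1.34, 1.29, 1.75 and 1.41 with peaks above that fold, in M-81E control and salt and Roma control and salt. Of tests of gene groups among peak genes, 1 of those fixed beforehand and 30 of the added ones passed with FPKM of at least 5 as background, and 0 of the former with peaks above that fold. Motif searches in whole peaks and in their central part were not run, because no genome sequence was used. Total read depth is unknown, and with 2 libraries per group changes near a log2 of 1 were seldom recovered in the simulation.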

Other observations

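Apart from dividing-cell markers, the gene groups here and their tests were set after the annotated functions had been read. Proton pumps, chaperones and hypoxia genes were among the groups with a peak more often than other expressed genes. Proton pumps had a peak for 82.6% of 23 members in both M-81E lists, 75.0% of 24 in Roma control and 83.3% of 24 in Roma salt (adjusted p = 0.0120, 0.0120, 0.000125 and 0.0360, Fisher's exact test). Hypoxia response genes had one for 70, 73.2, 52.5 and 76.2%, and heat response and protein folding genes for 67.2, 64.7, 44.2 and 68.2%, in M-81E control and salt and Roma control and salt. At matched expression the shares were 77.2, 74.9, 61.9 and 78.6% for proton pumps, 63.8, 65.6, 46.9 and 68.9% for hypoxia genes and 61.8, 62.0, 41.3 and 66.2% for heat response genes, so much of each excess went with expression. With FPKM of at least 5 as background, proton pumps passed only in Roma control (adjusted p = 0.0138), heat response genes only there too (0.0449), and hypoxia genes in none of the 4 lists. Water channels had a peak for 20.8% of members in M-81E salt and 26.1% in Roma salt (adjusted p = 0.0133 and 0.0190), where genes of matched expression had one for 65.6 and 65.8%. In M-81E control (31.8%, adjusted p = 0.182) and Roma control (20%, 0.502) they did not pass, and no difference between control and salt was tested. With FPKM of at least 5 as background water channels passed as lower in M-81E control too (adjusted p = 0.0235, Fisher's exact test), but not in Roma control (0.242). Suberin and Casparian strip genes had one for 20 and 23.5% in the same salt lists (adjusted p = 0.0477 and 0.0233; 54.25 and 49.3% at matched expression). In M-81E control (23.1%, adjusted p = 0.128) and Roma control (20%, 0.633) they did not pass, with like shares.

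Of dividing-cell markers, 7 of 11 had a peak in M-81E control and 2 of 11 in M-81E salt, and 3 of 11 in Roma control and 7 of 12 in Roma salt. In the larger nucleosome and mitosis group the shares were 52.6 and 32.9% in M-81E and 24.1 and 57.0% in Roma, control and salt in turn. Of all genes with FPKM of at least 1 they were 50.6 and 51.6% in M-81E and 31.1 and 56.8% in Roma. So the rise in Roma was like that of all such genes. Against that background the larger group passed, as lower, only in M-81E salt (adjusted p = 0.00629, Fisher's exact test). Differences between lists were not tested. Pyruvate decarboxylase, SORBI_3001G405500, an enzyme of ethanol fermentation, was at 1020.2 ± 164 in Roma control and 477 ± 26.5 in Roma salt (SD, n = 2; adjusted p = 0.427).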
